A study of Mus musculus with 16 samples.

How the data were processed

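RNA from TFH cells of 16 mouse samples was sequenced by the authors, 4 libraries in each of the groups WT, BCL6FC, BLIMP1FC and DKO. Per the labels, the mice were immunized with peanut protein and cholera toxin, RNA was prepared with the Qiagen RNeasy Plus Micro Kit and libraries with the KAPA mRNA HyperPrep Kit. Groups and replicate numbers were taken from the sample titles. The design speaks of different mice, but the labels do not say that each library is 1 animal or what a shared replicate number means, so no block was used and the p-values measure the spread between the samples of a group.

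The submitters' processing notes name FastQC, STAR, featureCounts, Subread, MultiQC and edgeR with build mm10, and versions were not given in the sources used here. The deposited table gives counts per gene and library, unnormalized, for 12117 genes. It was checked that every gene listed had over 0.5 CPM in at least 4 libraries, so genes below that level are not listed. The same table gives log2 RPKM by the authors, which was recomputed from the counts with TMM factors and a prior count of 0.25. It also gives the authors' log2 fold change and the authors' p-value, adjusted by Benjamini-Hochberg, for each pair of groups. Gene coordinates and exon lengths were taken from the deposited table, per the file headers, and the build from the labels.

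Total counts were 19440390, 19760919, 23768820 and 20458783 in WT 1 to 4, 22991597, 21344128, 20653426 and 24814648 in BCL6FC 1 to 4, 26159454, 30705669, 20445753 and 21819568 in BLIMP1FC 1 to 4, and 22143315, 24392310, 24402501 and 16484760 in DKO 1 to 4. TMM factors ran from 0.9488 to 1.0369. Replicate libraries had Pearson r of 0.977 to 0.9939 in log2 CPM and a chi-square per degree of freedom of 8.504 to 45.58, so no library was a copy of another of its group. With 4 samples against 4, the smallest two-sided p of an exact permutation test is 0.0286, so the permutation test of a single gene cannot pass a correction over all genes.

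Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust quasi-likelihood F test) in a single fit of 4 group means. The filter kept all 12117 genes. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. Log2 fold changes are those of the fit, their SE is approximate, and levels are TMM-scaled CPM, given as mean ± SD of the 4 libraries. The 7 comparisons were BCL6FC vs WT, BLIMP1FC vs WT, DKO vs WT, DKO vs BLIMP1FC, DKO vs BCL6FC, the mean of BCL6FC and DKO against that of WT and BLIMP1FC, and the interaction.

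The 13 biology lists (TFH programme, cytotoxic programme, Treg and TFR genes, Th1, Th2 and Th17 genes, inhibitory receptors and exhaustion genes, IL-2 and STAT5 response genes, type I interferon response genes, cell cycle genes, naive and recirculating T cell genes, immediate-early and stress genes, and cytokine and growth factor genes) were tested with camera of limma 3.58.1. The preset inter-gene correlation was 0.01, log2 CPM used a prior count of 2, and p-values were adjusted over the 13 lists. Camera with an estimated correlation and fry were run beside it. List members carry no expected sign, so the direction of a list is not by itself a gain or loss of the state it names. A list without a call may hold members that changed in both directions. Lists share members, such as Prdm1, Il2ra and 3 others between the Treg and TFR list and the IL-2 and STAT5 list. The title of the series names cytotoxic-like cells, so the choice of the cytotoxic list was not independent of the study. The 8 check lists (B cell and plasma cell, CD8 T cell, NK, innate and gamma delta T cell, myeloid and dendritic cell, erythroid and platelet, stromal and epithelial, sex-linked and mitochondrial) were described per library. Chemokine receptor, MHC class I, ribosomal protein, glycolysis, integrin, S100 and annexin, nuclear noncoding RNA and granulocyte precursor lists were chosen after seeing the data.

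Groups, comparisons, tests, the 13 and 8 lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule, the text may name, per comparison, up to 8 called genes in each direction with the largest changes among those with a mean of at least 5 CPM and groups that do not overlap the other's mean, up to 3 called members of each biology list, and Bcl6, Prdm1, Foxp3, Cxcr5, Pdcd1, Icos, Il21, Il4, Il10, Ifng, Gzmb, Eomes and Tbx21 whatever their p. The interaction took 5 in each direction. Cd8a was in the rule but is not listed in the table. Some genes that the rule allows are not reported here. Cd8b1, Fcer1g, Klrb1c, Cd68, Rn45s, Lars2, Malat1, Neat1, Xist, the granulocyte precursor genes and the genes of the added lists were named after their values were seen.

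The alternatives were DESeq2 1.42.0, RLE size factors, no filter, a filter of 5 CPM in 4 libraries (9775 genes), a replicate block, a fit of only the compared groups, camera with an estimated correlation, fry, and leaving out each library in turn. Leaving out WT 4 with BCL6FC 2, and BLIMP1FC 1 with BLIMP1FC 4, was added after seeing the data. Splits of the samples were counted for each comparison. The pipeline was tested on simulated data of BCL6FC vs WT. It recovered 85.1% of genes planted at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 7 of its 193 calls were not planted. With nothing planted it called 0 genes and 0 lists. Simulated genes varied independently of each other, so this does not show how often lists are called when members vary together. Planted genes had a mean of at least 5 CPM, so recovery of weaker genes was not tested.

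By the authors' deposited table, 1828 genes passed an adjusted p under 0.05 in BCL6FC vs WT, 941 in BLIMP1FC vs WT, 3727 in DKO vs WT, 5109 in DKO vs BLIMP1FC, 2801 in DKO vs BCL6FC and 4261 in BLIMP1FC vs BCL6FC. The calls of the edgeR quasi-likelihood fit shared 1500, 561, 3452, 4932 and 2474 genes with the first 5 of these, and the lowest Pearson r between the log2 fold changes was 0.9999. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. BLIMP1FC against BCL6FC was left out as a comparison because it changes both alterations at once. Reads shared between near-identical paralogs, such as Hspa1a and Hspa1b or members of the Ifit and H2 families, and exons that overlap on opposite strands, were not resolved by the deposited counts.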

Results

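RNA was sequenced from freshly isolated T follicular helper (TFH) cells, the CD4 T cells that help B cells in germinal centres, of mice given peanut protein with cholera toxin by the intragastric route 2 times. The series design names presence or loss of follicular regulatory T (TFR) cells as the difference between the mice. Its 16 libraries fell into 4 groups of 4, labelled WT (wild type), BCL6FC, BLIMP1FC and DKO. The labels do not expand FC or DKO and do not say in which cells a gene was altered, and DKO was taken as the line with both alterations. Depth ran from 16484760 counts in DKO 4 to 30705669 in BLIMP1FC 2, and 10303 of the 12117 listed genes reached a CPM (counts scaled to the library total) of at least 1 in all libraries.

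The gene names in the labels point to Bcl6, a transcriptional repressor needed for TFH and TFR cells, and to Prdm1, which encodes the repressor BLIMP1. Prdm1 (mm10, chromosome 10, 44437174 to 44458748, minus strand) had 9.37, 6.09, 13.8 and 22.4 CPM in WT 1 to 4, and 41.0, 46.4, 37.5 and 35.4 CPM in BCL6FC 1 to 4. It had 2.88, 3.68, 1.65 and 3.77 CPM in the libraries labelled BLIMP1FC, and 103, 64.8, 33.6 and 82.1 CPM in those labelled DKO. Bcl6 (mm10, chromosome 16, 23965052 to 23988612, minus strand) had 265, 328, 312 and 350 CPM in WT, and 292, 276, 319 and 273 CPM in BCL6FC. In BLIMP1FC it had 432, 343, 393 and 475 CPM, and in DKO 211, 301, 251 and 195 CPM. Prdm1 was thus lower than in WT in the libraries labelled BLIMP1FC and higher in those labelled DKO, while Bcl6 in BCL6FC lay within the range of WT. Whole-gene counts of TFH cells do not test a deletion made in another cell type, so the group labels were taken as given.

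Foxp3 (mm10, chromosome X, 7579676 to 7595243, plus strand) encodes the transcription factor that defines regulatory T cells, the lineage of TFR cells. It had 9.88, 16.5, 7.36 and 8.63 CPM in WT, and 0.229, 0.0974, 1.10 and 0.960 CPM in BCL6FC. The libraries labelled BLIMP1FC had 20.7, 15.5, 28.6 and 21.0 CPM, and those labelled DKO 0.591, 0.572, 0.203 and 0.433 CPM. Its exons overlap those of Ccdc22 on the opposite strand over 1770 bp, and the sources do not state whether counting used the strand.

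**Figure D1:**
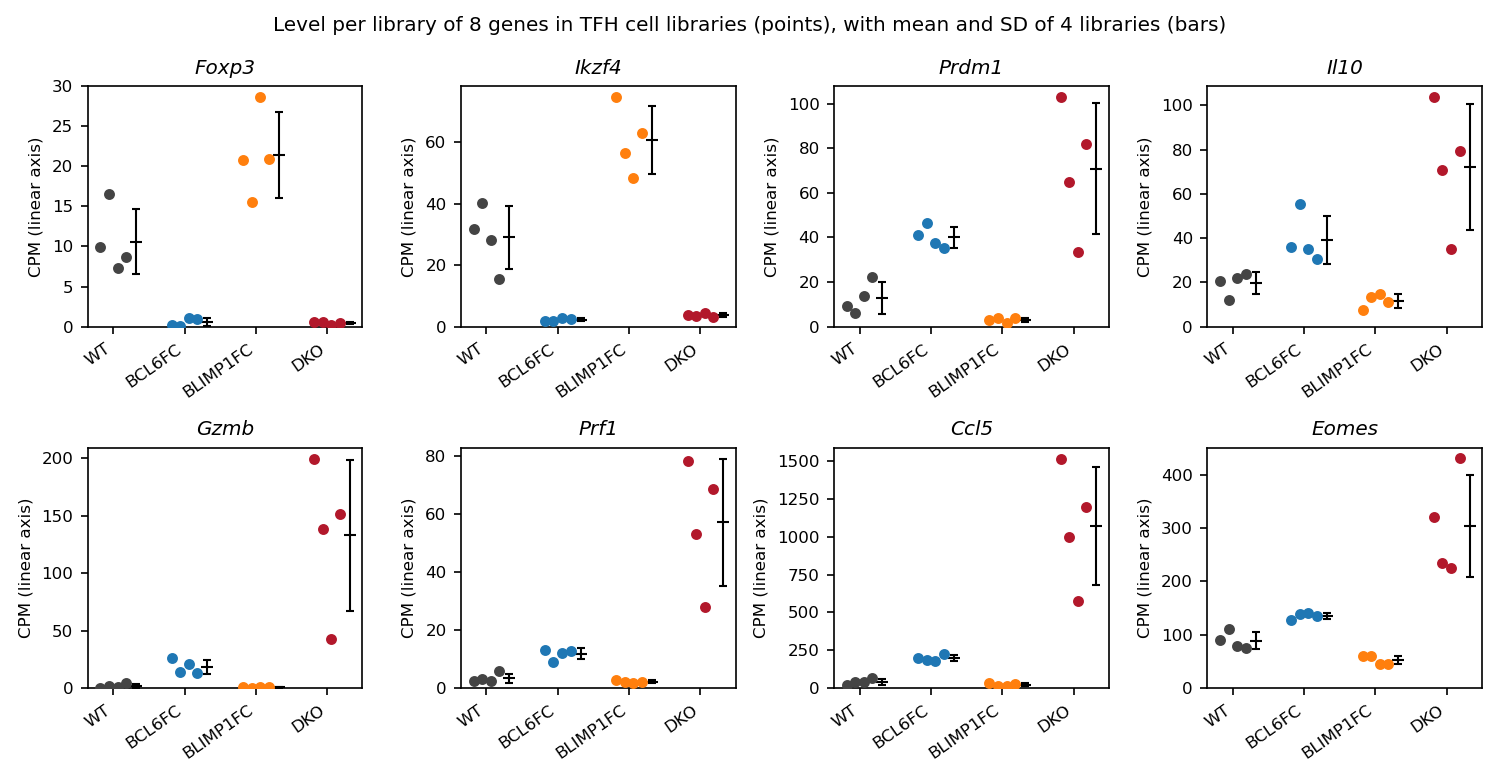
Level in CPM (linear axis) of 8 genes in each of the 16 libraries, points by group, with the mean and SD of 4 libraries as bars. Gzmb averaged 133 CPM in DKO and 2.00 CPM in WT, while Foxp3 averaged 0.45 CPM in DKO and 21.5 CPM in BLIMP1FC.

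Principal components of log2 CPM had 42.2% of the variance on the first component and 15.7% on the second. They placed BLIMP1FC and DKO apart from the other groups, but not all WT libraries apart from BCL6FC. On the first, WT 4 lay at 5.76, away from the other WT libraries at -24.74 to -18.06 and next to the BCL6FC libraries at 10.72 to 30.82. On the second, WT 4 lay at 20.17 and BCL6FC 2 at 20.94, and on the third at 16.57 and -16.47.

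**Figure D2:**
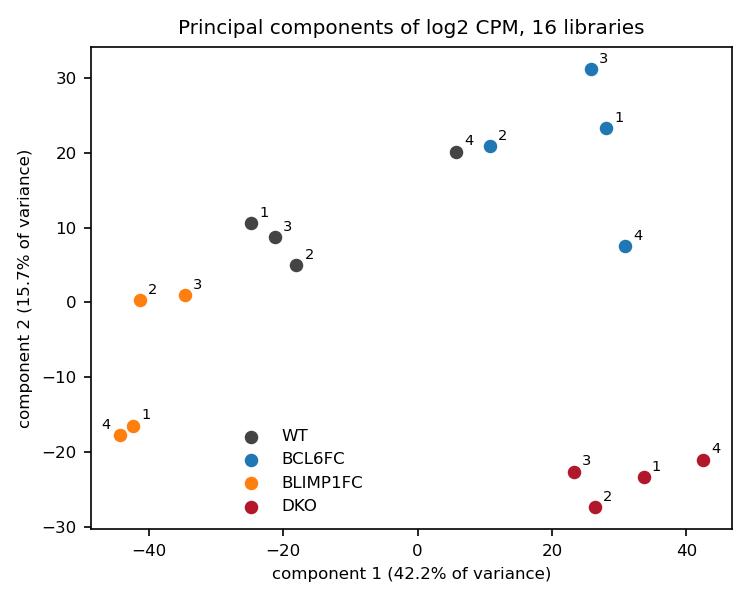
First and second principal components of log2 CPM for the 16 libraries, coloured by group and numbered by replicate. The BLIMP1FC libraries lie at -44.24 to -34.63 on the first component and the DKO libraries at 23.2 to 42.44.

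BCL6FC was compared with WT to ask how TFH cells differ in the line whose label names BCL6. In the libraries labelled BCL6FC, 11 of 26 Treg and TFR genes were lower and 2 higher, a list call lost with an estimated correlation (adjusted p = 0.143). Foxp3 fell from 10.6 ± 4.09 (SD, n = 4) to 0.596 ± 0.505 CPM (SD, n = 4), and Ikzf4, which encodes the Foxp3 partner Eos, from 29.1 ± 10.3 to 2.28 ± 0.461 CPM (SD, n = 4). Of 30 cytotoxic genes 10 were higher and 2 lower, a call also lost with an estimated correlation (0.26). Gzmb, which encodes granzyme B (mm10, chromosome 14, 56258858 to 56262260, minus strand), rose from 2.00 ± 1.93 to 18.5 ± 5.92 CPM, and the chemokine gene Ccl5 from 41.1 ± 18.8 to 199 ± 20.9 CPM (SD, n = 4). Type I interferon response genes had 29 of 37 higher (0.0618 with an estimated correlation), such as Isg15, which rose from 17.8 ± 0.94 to 31.1 ± 2.00 CPM.

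Of 26 measured Treg and TFR genes, 11 fell and 2 rose in BCL6FC (13 and 4 when adjusted over the list alone), with a list adjusted p of 1.76e-05 that was an adjusted p = 0.143 with an estimated correlation. Beside Foxp3 (log2 fold change -4.13, SE 0.44, adjusted p = 9.39e-05) and Ikzf4 (-3.67), Lrrc32, which encodes the TGF-beta binding protein GARP, fell by 4.11 on the log2 scale, and Swap70 fell by 1.77. The 2 members that rose were Prdm1 (log2 fold change 1.63, adjusted p = 0.0124) and Il10 (0.99, adjusted p = 0.04995). Markers of B and plasma cells were lower in the same libraries. Of 20 measured, 7 fell and 1 rose, and their summed level was 179.02 to 211.14 CPM in BCL6FC against 226.12 to 307.5 CPM in WT.

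The cytotoxic programme had 10 members higher and 2 lower of 30 measured in BCL6FC than in WT (12 and 2 when adjusted over the list alone; list adjusted p = 0.000558, and adjusted p = 0.26 with an estimated correlation). Gzmb had a log2 fold change of 3.21 (SE 0.58, adjusted p = 0.00372), Ccl5 of 2.27 and the granule gene Nkg7 of 1.36, while Cd160, a receptor of cytotoxic lymphocytes, fell by 1.49. Th1 genes had 8 of 18 members higher and none lower (9 and 0 when adjusted over the list alone), with a list adjusted p of 0.000189 that held with an estimated correlation at 0.0409. They included the chemokine receptor gene Cxcr3 (log2 fold change 0.73), whereas Ifng, the Th1 cytokine gene, had a log2 fold change of 0.08 (adjusted p = 0.768). The chemokine receptor gene Ccr2, which monocytes and effector T cells express, rose by 2.86 on the log2 scale and was the single myeloid marker past the test of 17 measured.

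Type I interferon response genes had 29 of 37 measured members higher and none lower (34 and 0 when adjusted over the list alone; list adjusted p = 3.91e-26, and adjusted p = 0.0618 with an estimated correlation). Examples were Oas1a and Bst2, both with a log2 fold change of 0.98, and Isg15 with 0.80. Naive and recirculating T cell genes had 5 of 19 higher and none lower (7 and 1 when adjusted over the list alone; list adjusted p = 0.00149, and adjusted p = 0.261 with an estimated correlation), among them Klf2 (1.32), a regulator of T cell trafficking, and its target S1pr1 (1.07), the lymph node egress receptor.

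The TFH programme was not shifted in a common direction as a list (adjusted p = 0.788), with 8 of 36 members higher and 5 lower (11 and 7 when adjusted over the list alone). Fry for changes in either direction gave an adjusted p of 3.88e-07. This was not particular to the TFH list, since the Th2 list had the same value and only the cell cycle list did not pass (0.586). Icos, a costimulatory receptor of TFH cells, rose by 0.51 on the log2 scale and Ly6a, a surface antigen of activated T cells, by 1.00. Cxcr5, the follicle homing receptor, had a log2 fold change of 0.15 (adjusted p = 0.529), Pdcd1, which encodes PD-1, of -0.28 (0.298), Il4 of -0.33 (0.496) and Bcl6 of -0.11 (0.613). Il21, Eomes, Tbx21 and Il10 passed the test narrowly, with log2 fold changes of 0.53, 0.60, 0.54 and 0.99. Each of these 4 calls was lost with the replicate number as a block (adjusted p of 0.0507 to 0.099) and when single libraries were left out. Il10 lost it without any of the 8, Eomes without any but WT 2, Il21 without any but WT 3, and Tbx21 without any but WT 4 and BCL6FC 2. The highest adjusted p was 0.138 for Il10 without WT 2, 0.114 for Eomes without WT 3, 0.127 for Il21 without BCL6FC 1 and 0.117 for Tbx21 without WT 2. Hspa1b, a heat shock gene of the immediate-early and stress list, was at 20.8 ± 1.65 CPM in BCL6FC against 3.10 ± 1.12 CPM in WT (SD, n = 4), while that list had no call. Hspa1b has a near-identical paralog, so its count is uncertain.

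Counts for the lists without a call in BCL6FC against WT were 0 higher and 1 lower of 14 Th2 genes, 2 and 0 of 10 Th17 genes, 1 and 3 of 18 inhibitory receptor and exhaustion genes, and 3 and 1 of 20 IL-2 and STAT5 response genes. The cell cycle list had 0 of 40 members past the test, the immediate-early and stress list 5 higher and 1 lower of 29, and the cytokine and growth factor list 4 and 1 of 24. In all, 1502 of 12117 genes changed in BCL6FC, 742 higher and 760 lower, and of these 93 were at least 2-fold higher and 284 at least 2-fold lower. Of those 284 genes, 185 were among the 20% of genes with the lowest abundance. The count was 745 without WT 2, 773 without WT 3 and 833 without BCL6FC 1. It was 751 with only the 8 libraries compared. It rose to 1922 without WT 4 and to 2244 without WT 4 and BCL6FC 2 together.

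**Figure D3:**
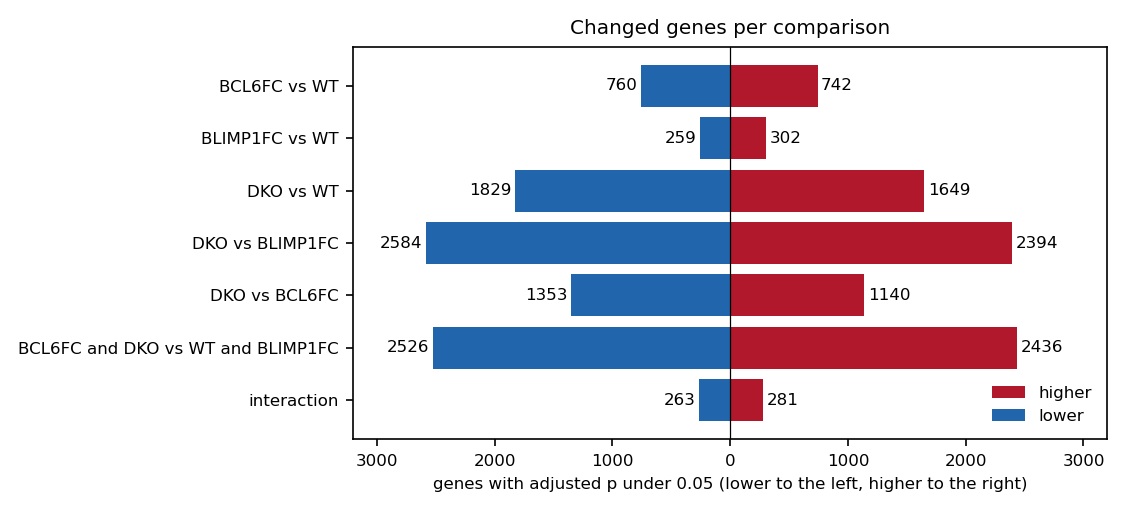
Number of genes with an adjusted p under 0.05 in each of 7 comparisons, higher to the right and lower to the left. DKO vs BLIMP1FC had 2394 genes higher and 2584 lower, and BLIMP1FC vs WT had 302 higher and 259 lower.

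BLIMP1FC was compared with WT to ask how TFH cells differ in the line whose label names BLIMP1. In the libraries labelled BLIMP1FC, 5 of 26 Treg and TFR genes and 4 of 10 Th17 genes were higher, and 14 of 37 interferon response and 5 of 19 naive and recirculating genes lower. With an estimated correlation the Th17 call held, and the other 3 were lost (0.19, 0.106 and 0.106). Ikzf4 rose from 29.1 ± 10.3 to 60.7 ± 11.1 CPM, a call lost with only the 8 libraries compared (adjusted p = 0.0579), and Itgae, the integrin chain CD103 of tissue-resident and regulatory T cells, had a log2 fold change of 1.92 (SE 0.27, adjusted p = 0.00172). Gzmk fell from 53.0 ± 11.4 to 21.7 ± 4.34 CPM (SD, n = 4). Prdm1 fell from 12.9 ± 7.05 to 2.99 ± 0.981 CPM (log2 fold change -2.09, SE 0.42, adjusted p = 0.0154), a call lost without WT 4 (adjusted p = 0.0522) or BLIMP1FC 1 (0.0523). The call for Gzmk was lost without BLIMP1FC 4 (adjusted p = 0.051).

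Treg and TFR genes had 5 of 26 members higher and 1 lower in BLIMP1FC than in WT (14 and 5 when adjusted over the list alone; list adjusted p = 0.000151, and adjusted p = 0.19 with an estimated correlation). Foxp3 itself averaged 21.5 ± 5.37 CPM against 10.6 ± 4.09 CPM (SD, n = 4), which did not pass the test (adjusted p = 0.0952). Th17 genes had 4 of 10 higher and 1 lower (8 and 1 when adjusted over the list alone), with a list adjusted p of 2.08e-05 that held with an estimated correlation at 0.0426. Lgals3, which encodes galectin-3, rose by 1.67 on the log2 scale. Il23r, the receptor for the Th17 cytokine IL-23, had a log2 fold change of 2.82 (adjusted p = 0.0191), a call lost without WT 3, WT 4, BLIMP1FC 1 or BLIMP1FC 4, with adjusted p of 0.0519 to 0.0666. Il23r also counts among the markers of NK, innate and gamma delta T cells, of which 2 of 6 measured rose.

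Type I interferon response genes had no member higher and 14 of 37 lower in BLIMP1FC (0 and 26 when adjusted over the list alone; list adjusted p = 2.41e-18, and adjusted p = 0.106 with an estimated correlation). Ifit1 fell by 0.88 on the log2 scale, Ifit1bl1 by 1.64 and Isg15 by 0.39, the last a call lost with only the 8 libraries compared (adjusted p = 0.0615). Naive and recirculating T cell genes had 5 of 19 lower and none higher (13 and 0 when adjusted over the list alone; list adjusted p = 1.6e-08, and adjusted p = 0.106 with an estimated correlation), including Bach2, a repressor of effector differentiation, which fell by 0.71. Il12rb2, the signalling chain of the IL-12 receptor, fell by 1.97 and the receptor gene Gpr55 by 2.14.

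The TFH programme had 3 of 36 members higher and 2 lower in BLIMP1FC vs WT (9 and 6 when adjusted over the list alone; list adjusted p = 0.0354, and adjusted p = 0.374 with an estimated correlation). Its call was lost without WT 1 (0.0544), WT 4 (0.0554), BLIMP1FC 1 (0.0667) or BLIMP1FC 4 (0.0757). Inhibitory receptor and exhaustion genes had 1 of 18 higher and none lower (2 and 0 when adjusted over the list alone; list adjusted p = 0.0315, and adjusted p = 0.3 with an estimated correlation). That call was lost without WT 4 (0.122), BLIMP1FC 2 (0.0622) or BLIMP1FC 4 (0.0581). In the TFH list Ly6a fell by 0.71 on the log2 scale, while Bcl6 had a log2 fold change of 0.39 (adjusted p = 0.0878), Pdcd1 of 0.44 (0.145), Icos of 0.29 (0.117) and Cxcr5 of -0.20 (0.484). Il4 had 0.84 (0.102), Ifng -0.43 (0.118), Il10 -0.77 (0.202) and Gzmb -1.38 (0.405).

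Transcripts of granulocyte precursors were present in some BLIMP1FC libraries. Prg2, an eosinophil granule protein gene, averaged 20.2 ± 20.6 CPM and the neutrophil enzyme gene Mpo 15.9 ± 15.8 CPM (SD, n = 4), against 0.0558 and 0.146 CPM in WT. The sum over 10 such genes was 170 CPM in BLIMP1FC 1, 144 in BLIMP1FC 4, 19.4 in BLIMP1FC 2 and 0.142 in BLIMP1FC 3. Prg2 (adjusted p = 0.0191) lost its call without BLIMP1FC 1 (0.0511) or WT 4 (0.0746). Mpo (adjusted p = 0.0256) lost it without any 1 of the 8 libraries except BLIMP1FC 2 and BLIMP1FC 3, with adjusted p of 0.0527 to 0.0955. The sum over 17 measured myeloid markers was 194.34 and 239.34 CPM in BLIMP1FC 1 and 4 and 61.4 to 103.31 CPM in WT.

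Without BLIMP1FC 1 and 4 together, the calls in BLIMP1FC vs WT for Ikzf4, Gzmk, Prdm1, Il23r, Ifit1, Ifit1bl1, Isg15, Bach2, Il12rb2, Gpr55, Ly6a, Prg2 and Mpo were lost, with adjusted p of 0.0659 to 0.325. Log2 fold changes grew in size for Gzmk (-1.38), Prdm1 (-2.22), Ifit1 (-1.01), Ifit1bl1 (-1.89), Isg15 (-0.48), Il12rb2 (-2.12) and Ly6a (-0.78). They shrank for Ikzf4 (0.86), Il23r (2.33), Bach2 (-0.57), Gpr55 (-1.73), Prg2 (5.49) and Mpo (3.94). Fewer libraries also lower the power, so a lost call alone does not show dependence on these libraries.

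In all, 561 genes changed in BLIMP1FC against WT, 302 higher and 259 lower, with 123 at least 2-fold higher and 54 at least 2-fold lower. Counts for the lists without a call were 0 higher and 3 lower of 30 cytotoxic genes, 0 and 3 of 18 Th1 genes, 1 and 1 of 14 Th2 genes, 0 and 3 of 20 IL-2 and STAT5 response genes, 0 and 1 of 40 cell cycle genes, 1 and 3 of 29 immediate-early and stress genes, and 1 and 1 of 24 cytokine genes. The number of changed genes was 183 without BLIMP1FC 1 and 189 without BLIMP1FC 4, but 537 without BLIMP1FC 2 and 654 without BLIMP1FC 3. Each of these fits lacked 1 library of the same group, so the number of libraries alone does not account for their difference. The number of changed genes was 202 without WT 4, 340 without WT 3 and 8 without BLIMP1FC 1 and 4 together. It was 253 without WT 4 and BCL6FC 2, 312 with only the 8 libraries compared and 965 by DESeq2.

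DKO was compared with WT to ask how TFH cells differ in the line taken to carry both alterations. In the libraries labelled DKO, 21 of 30 cytotoxic genes were higher and none lower. Gzmb rose from 2.00 ± 1.93 to 133 ± 65.5 CPM, a 66.7-fold change by the fit, and Ccl5 from 41.1 ± 18.8 to 1071 ± 391 CPM (SD, n = 4). Prf1, which encodes the pore-forming protein perforin (mm10, chromosome 10, 61297836 to 61304263), rose 16.5-fold, from 3.47 ± 1.56 to 57.2 ± 22.0 CPM. Of 26 Treg and TFR genes 13 were lower and 4 higher, a call lost with an estimated correlation (0.255), with Foxp3 at 0.45 ± 0.179 CPM and Ikzf4 at 3.79 ± 0.596 CPM in DKO. Cell cycle genes had 31 of 40 higher and immediate-early and stress genes 21 of 29 lower, 2 calls also lost with an estimated correlation (0.255 and 0.187).

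The cytotoxic programme had 21 of 30 members higher and none lower in DKO than in WT (21 and 0 when adjusted over the list alone), a median log2 fold change of 1.22 and a list adjusted p of 5.97e-15 that held with an estimated correlation at 0.0196. Gzmb had a log2 fold change of 6.06 (SE 0.59, adjusted p = 2.04e-05), Prf1 of 4.04 (adjusted p = 4.24e-06) and Nkg7 of 3.35 (adjusted p = 7.52e-07). Eomes (mm10, chromosome 9, 118478189 to 118486132), a T-box factor of cytotoxic lymphocytes, rose from 89.2 ± 15.8 to 303 ± 95.7 CPM. Cd8b1, the single CD8 T cell marker measured, averaged 6.45 ± 2.44 CPM in DKO and 5.71 ± 1.76 CPM in WT (adjusted p = 0.603), and Cd8a is not listed in the table. None of the 6 measured markers of NK, innate and gamma delta T cells passed the test.

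Treg and TFR genes had 13 of 26 members lower and 4 higher in DKO (14 and 5 when adjusted over the list alone; list adjusted p = 0.00476, and adjusted p = 0.255 with an estimated correlation). Foxp3 fell by 4.55 on the log2 scale, Lrrc32 by 5.89, Ikzf4 by 2.93 and Gpr83, a receptor enriched in regulatory T cells, by 3.10. Among the members that rose were Prdm1 (2.45), Il10 (1.88) and Entpd1 (2.02), which encodes the ectoenzyme CD39. The inhibitory receptor gene Havcr2, which encodes TIM-3, rose from 1.03 ± 0.778 to 33.2 ± 17.2 CPM (SD, n = 4), while the list of inhibitory receptor and exhaustion genes had 3 of 18 higher and 5 lower and no call (adjusted p = 0.978).

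Th1 genes had 6 of 18 members higher and 1 lower in DKO (6 and 1 when adjusted over the list alone; list adjusted p = 0.0074, and adjusted p = 0.142 with an estimated correlation), with the cytokine gene Tnf at a log2 fold change of -1.01. Ifng had 0.21 (adjusted p = 0.296) and Tbx21, which encodes T-bet, -0.09 (0.714). Th17 genes had 4 of 10 higher and none lower (4 and 0 when adjusted over the list alone; list adjusted p = 0.016, and adjusted p = 0.187 with an estimated correlation), Lgals3 by 1.79. Type I interferon response genes had 21 of 37 higher and 1 lower (24 and 2 when adjusted over the list alone; list adjusted p = 3.62e-07, and adjusted p = 0.255 with an estimated correlation), by 0.62 for Ifi47 and 0.41 for Gbp2, both interferon-induced GTPases.

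Cell cycle genes had 31 of 40 members higher and none lower in DKO than in WT (36 and 1 when adjusted over the list alone; list adjusted p = 4.15e-13, and adjusted p = 0.255 with an estimated correlation). Ccna2, which encodes cyclin A2, had a log2 fold change of 1.60, Cdk1 of 1.36 and the spindle gene Prc1 of 1.28. Immediate-early and stress genes had 21 of 29 lower and 1 higher (24 and 1 when adjusted over the list alone; list adjusted p = 2.93e-08, and adjusted p = 0.187 with an estimated correlation). Nr4a1, induced by T cell receptor signals, fell by 1.19 and the stress phosphatase subunit gene Ppp1r15a by 0.80, and the kinase gene Pim1, from the IL-2 and STAT5 list, fell by 1.01.

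The TFH programme had 8 of 36 members higher and 7 lower in DKO and no list call (adjusted p = 0.592). Ly6a had a log2 fold change of 1.26 and Izumo1r, the folate receptor FR4 of TFH and regulatory T cells, of -0.64. Bcl6 (log2 fold change -0.39, adjusted p = 0.03) and Cxcr5 (0.38, adjusted p = 0.0432) passed, but Bcl6 lost its call without WT 2, WT 3, WT 4, DKO 1 or DKO 4, with adjusted p of 0.058 to 0.0933. Cxcr5 lost it without WT 1, WT 2, WT 3, DKO 1, DKO 2 or DKO 3, with adjusted p of 0.0595 to 0.125, and with the replicate number as a block (0.0539). Il4 had a log2 fold change of -0.19 (adjusted p = 0.639) and Icos of 0.20 (0.146). Other lists without a call had 1 higher and 5 lower of 14 Th2 genes, 3 and 3 of 20 IL-2 and STAT5 response genes, 3 and 3 of 19 naive and recirculating genes, and 4 and 2 of 24 cytokine genes. In all, 3478 genes changed, 1649 higher and 1829 lower, with 296 at least 2-fold higher and 426 at least 2-fold lower. The myeloid marker sum was 117.25 to 201.94 CPM in DKO, which includes 73.9 CPM of Ccr2 on average. Of 17 measured myeloid markers 2 were higher and none lower, Ccr2 and Cd68, which rose from 11.6 ± 1.12 to 29.2 ± 6.68 CPM (adjusted p = 1.72e-05).

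**Figure D4:**
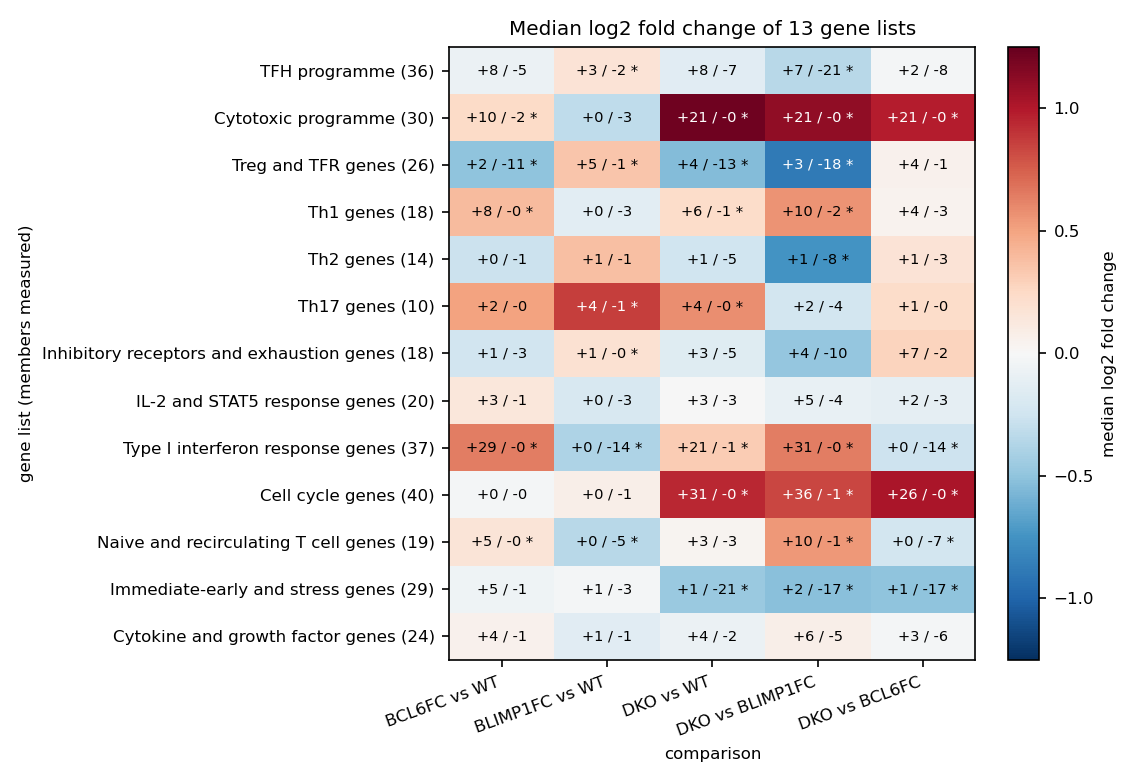
Median log2 fold change (colour) of 13 gene lists in 5 comparisons, with the number of members higher and lower in each cell and a star where the list adjusted p was under 0.05 at the preset correlation. The cytotoxic programme had 21 members higher and 0 lower in each of the 3 comparisons of DKO.

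DKO was compared with BLIMP1FC to ask what the BCL6 alteration adds to the BLIMP1 line, in libraries that share none with BCL6FC against WT. In the libraries labelled DKO, 21 of 30 cytotoxic genes were higher and 18 of 26 Treg and TFR genes lower, and both calls were lost with an estimated correlation (0.0561 and 0.118). Ccl5 was 23.1 ± 10.1 CPM in BLIMP1FC and 1071 ± 391 CPM in DKO, and Prf1 2.27 ± 0.383 and 57.2 ± 22.0 CPM (SD, n = 4). Lrrc32 fell from 31.5 ± 8.14 to 0.183 ± 0.15 CPM. Prdm1 rose by 4.54 on the log2 scale (SE 0.43, adjusted p = 5.62e-06), from the low level of the libraries labelled BLIMP1FC.

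The cytotoxic programme had 21 of 30 members higher and none lower in DKO than in BLIMP1FC (22 and 1 when adjusted over the list alone; list adjusted p = 1.98e-11, and adjusted p = 0.0561 with an estimated correlation), with Gzmb at a log2 fold change of 7.44 and Gzmk at 3.96. Treg and TFR genes had 18 of 26 lower and 3 higher (18 and 4 when adjusted over the list alone; list adjusted p = 1.96e-05, and adjusted p = 0.118 with an estimated correlation). Foxp3 fell by 5.56 on the log2 scale and Ccr8, a chemokine receptor of effector regulatory T cells, by 3.53. Th1 genes had 10 of 18 higher and 2 lower (10 and 3 when adjusted over the list alone; list adjusted p = 0.00373, and adjusted p = 0.108 with an estimated correlation), including Cxcr3 (1.30), Ifng (0.64) and Tbx21 (0.63). Th2 genes had 8 of 14 lower and 1 higher (8 and 1 when adjusted over the list alone; list adjusted p = 0.0176, and adjusted p = 0.118 with an estimated correlation), including Il4 (-1.03) and the basic leucine zipper factor Nfil3 (-1.77). Without BLIMP1FC 1 and 4 together, the Th2 call was lost (adjusted p = 0.07), as were those for Tbx21 (log2 fold change 0.33, adjusted p = 0.0866) and Il4 (-0.54, 0.172).

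The TFH programme had 21 of 36 members lower and 7 higher in DKO vs BLIMP1FC (21 and 7 when adjusted over the list alone; list adjusted p = 0.045, and adjusted p = 0.488 with an estimated correlation). This call was lost without BLIMP1FC 1 (0.0684), BLIMP1FC 4 (0.0906), DKO 1 (0.0554), DKO 3 (0.0542) or DKO 4 (0.124). Bcl6 fell from 411 ± 56.1 to 239 ± 47.3 CPM (log2 fold change -0.78, adjusted p = 0.000194) and the inhibitory receptor gene Btla by 0.84. Cxcr5 rose by 0.58 and Selplg, which encodes the selectin ligand PSGL-1, by 1.28. The list gives its members no expected sign, so it does not tell a gain from a loss of TFH identity. Pdcd1 had a log2 fold change of -0.48 (adjusted p = 0.0314), lost without BLIMP1FC 1 or 4 or DKO 1, 3 or 4, with adjusted p of 0.0515 to 0.0967.

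Type I interferon response genes had 31 of 37 members higher and none lower in DKO than in BLIMP1FC (33 and 0 when adjusted over the list alone; list adjusted p = 5.88e-15, and adjusted p = 0.118 with an estimated correlation), such as Ifi47 (1.04) and Gbp2 (0.77). Cell cycle genes had 36 of 40 higher and 1 lower (37 and 1 when adjusted over the list alone; list adjusted p = 5.86e-11, and adjusted p = 0.291 with an estimated correlation), such as Prc1 (1.35). Naive and recirculating genes had 10 of 19 higher and 1 lower (11 and 1 when adjusted over the list alone; list adjusted p = 0.00138, and adjusted p = 0.291 with an estimated correlation). Immediate-early and stress genes had 17 of 29 lower and 2 higher (17 and 2 when adjusted over the list alone; list adjusted p = 0.000314, and adjusted p = 0.291 with an estimated correlation), such as the phosphatase gene Dusp1 (-0.94). Il10 rose by 2.65 on the log2 scale. Lists without a call had 2 higher and 4 lower of 10 Th17 genes, 4 and 10 of 18 inhibitory receptor genes, 5 and 4 of 20 IL-2 and STAT5 genes, and 6 and 5 of 24 cytokine genes. In all, 4978 genes changed, 2394 higher and 2584 lower, with 395 at least 2-fold higher and 851 at least 2-fold lower. Markers of granulocyte precursors moved with these groups, Mpo by -4.14 and Prg2 by -5.62, and without BLIMP1FC 1 and 4 together both calls were lost (-1.43, adjusted p = 0.386, and -2.82, 0.12). Other markers and RNAs outside the lists differed too in DKO vs BLIMP1FC. Malat1 (-1.07, adjusted p = 0.00157), Neat1 (-1.77, 0.000289) and Xist (-1.16, 0.00726) were lower and Cd68 higher (0.88, 0.000155), and 2 of 5 erythroid and platelet markers and 2 of 6 markers of NK, innate and gamma delta T cells were lower. Over all genes 41.08% changed, and the marker counts were not tested against that share.

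DKO was compared with BCL6FC to ask what the BLIMP1 alteration adds to the BCL6 line. Both groups had low Foxp3. In DKO 21 of 30 cytotoxic genes and 26 of 40 cell cycle genes were higher, and with an estimated correlation only the cytotoxic call held (0.0326, against 0.431 for the cell cycle). Gzmb rose from 18.5 ± 5.92 to 133 ± 65.5 CPM, Nkg7 from 43.5 ± 8.84 to 172 ± 46.5 CPM and Havcr2 from 3.67 ± 0.426 to 33.2 ± 17.2 CPM (SD, n = 4). Interferon response genes had 14 of 37 lower, a call lost with an estimated correlation (0.431), and the heat shock gene Hspa1b was at 1.45 ± 0.744 CPM in DKO against 20.8 ± 1.65 CPM in BCL6FC.

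The cytotoxic programme had 21 of 30 members higher and none lower in DKO than in BCL6FC (23 and 1 when adjusted over the list alone), with a list adjusted p of 2.52e-13 that held with an estimated correlation at 0.0326. Gzmb had a log2 fold change of 2.84 (SE 0.47, adjusted p = 0.00193), Prf1 of 2.26, Klrg1, a receptor of terminal effector cells, of 2.76 and Eomes of 1.16, and Adgrg1, expressed by cytotoxic lymphocytes, rose by 2.83. Cell cycle genes had 26 of 40 higher and none lower (34 and 0 when adjusted over the list alone; list adjusted p = 7.09e-15, and adjusted p = 0.431 with an estimated correlation), such as Ccnb1 (1.57), which encodes cyclin B1, and Ube2c (1.64). Treg and TFR genes had 4 of 26 higher and 1 lower and no call (adjusted p = 0.394), with Entpd1 at 1.49 and Penk, the enkephalin precursor gene, at 1.64.

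Type I interferon response genes had 14 of 37 members lower and none higher in DKO than in BCL6FC (17 and 1 when adjusted over the list alone; list adjusted p = 1.88e-06, and adjusted p = 0.431 with an estimated correlation), such as Isg15 (-0.55) and Bst2 (-0.66). Immediate-early and stress genes had 17 of 29 lower and 1 higher (21 and 1 when adjusted over the list alone; list adjusted p = 2.68e-10, and adjusted p = 0.198 with an estimated correlation), such as Ppp1r15a (-0.74). In DKO vs BCL6FC, naive and recirculating genes had 7 of 19 lower and none higher (7 and 0 when adjusted over the list alone; list adjusted p = 0.00672, and adjusted p = 0.431 with an estimated correlation), such as Bach2 (-0.69), a call lost without BCL6FC 4 (0.0528). Il12rb2 fell by 1.86 on the log2 scale and Tbx21 by 0.62, while Prdm1 had a log2 fold change of 0.82 (adjusted p = 0.107), Il10 of 0.88 (0.0514), Bcl6 of -0.28 (0.124) and Cxcr5 of 0.24 (0.212).

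Lists without a call in DKO against BCL6FC had 2 higher and 8 lower of 36 TFH genes, 4 and 3 of 18 Th1 genes, 1 and 3 of 14 Th2 genes, 1 and 0 of 10 Th17 genes, 7 and 2 of 18 inhibitory receptor genes, 2 and 3 of 20 IL-2 and STAT5 genes, and 3 and 6 of 24 cytokine genes. In all, 2493 genes changed, 1140 higher and 1353 lower, with 274 at least 2-fold higher and 147 at least 2-fold lower. Markers of other cells and RNAs outside the lists also differed. In DKO vs BCL6FC, 3 of 20 B and plasma cell markers and 3 of 17 myeloid markers were higher, Cd68 among them (1.23, adjusted p = 0.000203), and 2 of 5 erythroid and platelet markers lower. Over all genes 20.57% changed, and the marker counts were not tested against that share. Rn45s (-1.93, adjusted p = 0.00936), Lars2 (-1.54, 0.0484) and Malat1 (-1.17, 0.00361) were lower. The count of changed genes was 1392 without BCL6FC 3, 1621 without DKO 2 and 1654 without DKO 3.

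The mean of BCL6FC and DKO was set against the mean of WT and BLIMP1FC to give the average difference of the lines taken to carry the BCL6 alteration. A call here does not show that both lines changed. Among the results given below, the cell cycle and Th2 lists had no call in BCL6FC vs WT. The same holds, for example, for Ifng, Bcl6, Pdcd1, Il4, Cxcr5, Cd68, Neat1 and Xist. In their libraries 17 of 26 Treg and TFR genes were lower and 4 higher, and 19 of 30 cytotoxic genes higher and 2 lower, and both calls were lost with an estimated correlation (0.0956 and 0.0669). Ikzf4 (mm10, chromosome 10, 128632415 to 128645993) had a log2 fold change of -3.83 (SE 0.18, adjusted p = 5.92e-09), Foxp3 of -4.85 (adjusted p = 1.35e-07) and Ccr8 of -2.99. Gzmb, Ccl5, Prf1 and Prdm1 had log2 fold changes of 5.33, 3.90, 3.21 and 3.09. Il10 rose by 1.82 and Ifng by 0.36, and Bcl6 fell by 0.45 (adjusted p = 0.000885), Pdcd1 by 0.38 and Il4 by 0.68. Without BLIMP1FC 1 and 4 together, the calls in this contrast for Ifng (adjusted p = 0.054), Pdcd1 (-0.26, 0.107) and Il4 (-0.44, 0.0901) were lost.

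Across all 16 libraries the cytotoxic programme had 19 of 30 members higher and 2 lower (21 and 2 when adjusted over the list alone; list adjusted p = 9.76e-09, and adjusted p = 0.0669 with an estimated correlation). Treg and TFR genes had 17 of 26 lower and 4 higher (18 and 4 when adjusted over the list alone; list adjusted p = 4.79e-06, and adjusted p = 0.0956 with an estimated correlation). For Th1 genes 11 of 18 were higher and 1 lower (11 and 1 when adjusted over the list alone; list adjusted p = 0.00069, and adjusted p = 0.0669 with an estimated correlation), Cxcr3 by 1.02. For Th2 genes 7 of 14 were lower and 1 higher (8 and 1 when adjusted over the list alone; list adjusted p = 0.0239, and adjusted p = 0.13 with an estimated correlation), Il13 by -1.56. The Th2 call was lost without BLIMP1FC 1 and 4 together (adjusted p = 0.0542 in BCL6FC and DKO vs WT and BLIMP1FC). Interferon response genes had 33 of 37 higher and none lower (34 and 0 when adjusted over the list alone; list adjusted p = 2.43e-20, and adjusted p = 0.0822 with an estimated correlation), Isg15 by 0.72.

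In the same contrast, cell cycle genes had 18 of 40 members higher and 1 lower (19 and 1 when adjusted over the list alone; list adjusted p = 2.55e-06, and adjusted p = 0.436 with an estimated correlation), Prc1 by 0.81. Naive and recirculating genes had 8 of 19 higher and 1 lower (8 and 1 when adjusted over the list alone; list adjusted p = 0.000507, and adjusted p = 0.246 with an estimated correlation), S1pr1 by 0.99. The TFH programme had 12 of 36 higher and 18 lower and no call (adjusted p = 0.238), with Gpr183, the oxysterol receptor EBI2, at 0.94 and Cxcr5 at 0.36. Other lists without a call had 4 higher and 1 lower of 10 Th17 genes, 4 and 9 of 18 inhibitory receptor genes, 6 and 3 of 20 IL-2 and STAT5 genes, 6 and 14 of 29 immediate-early and stress genes, and 7 and 4 of 24 cytokine genes. Of markers of other cells, 2 of 20 B and plasma cell markers were higher and 5 lower. For NK, innate and gamma delta T cells 1 of 6 was higher and 2 lower, and for stromal and epithelial markers 1 of 4 and 2. Neat1 had -1.07 (adjusted p = 0.000699), Xist -0.82 (0.00656) and Cd68 0.49 (0.00106). In all, 4962 genes changed (40.95%), 2436 higher and 2526 lower, with 210 at least 2-fold higher and 553 at least 2-fold lower.

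The interaction tested whether the effect of the BCL6 alteration differed between the BLIMP1 line and wild type. It was larger in the BLIMP1 line for Eomes (difference of log2 fold changes 1.91, SE 0.25, adjusted p = 0.00204), Ccl5 (3.26, adjusted p = 0.00704), Havcr2 (3.60, adjusted p = 0.0123), Prdm1 (2.91, adjusted p = 0.0137) and Ctla2a (3.50), and lower for Hspa1b (-3.33, adjusted p = 0.000545). Granulocyte precursor genes had larger negative values, -11.04 for Prg2 (adjusted p = 0.0206) and -8.52 for Mpo (0.031). Gzmb had 4.23 (adjusted p = 0.027), a call lost without WT 2, WT 4 or BLIMP1FC 2, with adjusted p of 0.0554 to 0.0909 and a log2 value of 3.38 without WT 4. Il10 (1.65, adjusted p = 0.0474) and Bcl6 (-0.67, adjusted p = 0.0439) passed narrowly, and both calls were lost with the replicate number as a block (0.0792 and 0.0567). Il10 lost its call without any 1 library except WT 2, BCL6FC 2, BCL6FC 4, BLIMP1FC 3 and DKO 3, with adjusted p of 0.0647 to 0.0925. Bcl6 lost it without any 1 except WT 4, BCL6FC 4, BLIMP1FC 2, BLIMP1FC 3 and DKO 2, with adjusted p of 0.0637 to 0.0889. For Foxp3 it was -1.44 (adjusted p = 0.224). Havcr2 lost its call without WT 4 and BCL6FC 2 together (2.967, adjusted p = 0.0567). Prdm1 lost its call without BLIMP1FC 1 and 4 together (0.0551), though its value of 3.045 there was not smaller than in the full fit.

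The interaction for the cytotoxic programme had 13 of 30 members past the test, all positive (17 when adjusted over the list alone), with a list adjusted p of 2.16e-14 that held with an estimated correlation at 0.0245. Cell cycle genes had 2 of 40 positive (27 when adjusted over the list alone; list adjusted p = 6.84e-15, and adjusted p = 0.357 with an estimated correlation). Immediate-early and stress genes had 5 of 29 negative and 1 positive (14 and 2 when adjusted over the list alone; list adjusted p = 2.98e-07, and adjusted p = 0.357 with an estimated correlation). The TFH programme had 3 of 36 negative and 1 positive (3 and 1 when adjusted over the list alone; list adjusted p = 0.0158, and adjusted p = 0.469 with an estimated correlation). In the interaction (DKO minus BLIMP1FC) minus (BCL6FC minus WT), the TFH call was lost without BCL6FC 4 (0.0637), BLIMP1FC 4 (0.0534) or DKO 4 (0.0871).

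Counts positive and negative in the interaction were 3 and 1 of 26 Treg and TFR genes, 3 and 1 of 18 Th1 genes, 0 and 1 of 14 Th2 genes, 1 and 0 of 10 Th17 genes, 2 and 0 of 18 inhibitory receptor genes, 2 and 1 of 20 IL-2 and STAT5 genes, 1 and 0 of 37 interferon genes, 0 and 0 of 19 naive genes, and 3 and 1 of 24 cytokine genes. Outside these lists, 5 of 10 granulocyte precursor genes, chosen after their values were seen, were negative and 0 positive in the interaction. Of 20 B and plasma cell markers, 3 were positive and 0 negative. Malat1 had -1.50 (adjusted p = 0.0181) and Cd68 0.78 (0.0395). In all, 544 genes passed, 281 positive and 263 negative. The number was 348 without WT 4, 271 without WT 3, 212 without WT 2, 239, 259 and 237 without BCL6FC 1, 2 and 3, and 1478 without BCL6FC 4. It was 282 without BLIMP1FC 1, 235 without BLIMP1FC 2, 250, 340, 341 and 209 without DKO 1 to 4, and 1132 by DESeq2.

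BCL6FC vs WT and DKO vs BLIMP1FC share no library, and their log2 fold changes had a Spearman rho of 0.535 across 12117 genes, which are not independent replicates. Of 742 genes higher in BCL6FC, 512 were also higher in DKO than in BLIMP1FC, where 146.6 would be shared by independent lists, and 9 were lower. Of 760 genes lower in BCL6FC, 567 were also lower in DKO, where 162.1 would be shared, and 3 were higher. The other pair without a shared library, BLIMP1FC vs WT and DKO vs BCL6FC, had a rho of 0.202, with 55 of 302 higher genes shared (28.4 by independence) and 57 of 259 lower genes shared (28.9). Log2 fold changes had a rho with abundance of 0.3 and 0.17 in the first pair and -0.16 and -0.17 in the second. After removing group means, BCL6FC and BLIMP1FC libraries of the same number correlated at r of 0.18 to 0.32. The numbers by independence take neither into account.

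The median, mean and test of a list without a call differed in sign in several comparisons. In BCL6FC vs WT the TFH list had a median of -0.07 and a mean of -0.02 with an upward test, and the immediate-early list a median of -0.06 and a mean of 0.19. In BLIMP1FC vs WT the cell cycle list had a median of 0.07 and a downward test. In DKO vs WT the median was negative and the mean positive for inhibitory receptor genes (-0.15 and 0.07), IL-2 and STAT5 genes (-0.01 and 0.33) and cytokine genes (-0.08 and 0.08), with a downward test for each. In DKO vs BLIMP1FC the IL-2 and STAT5 list had -0.09 and 0.62 with an upward test. In DKO vs BCL6FC the Th2 list had a median of 0.17 and a downward test, and the cytokine list -0.02 and 0.03 with a downward test. In the contrast of means the Th17 list had 0.09 and -0.08 with an upward test, and in the interaction the inhibitory receptor list had -0.04 and 0.12 with an upward test, and the cytokine list a median just below 0 and a mean of 0.12.

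Markers of other cell types were measured beside these groups. The B and plasma cell sum was 222.58 to 259.42 CPM in BLIMP1FC and 248.87 to 367.49 CPM in DKO. Of its 20 measured genes, 4 fell and 0 rose in BLIMP1FC vs WT, and 5 fell and 2 rose in DKO vs WT. Their median log2 fold change against WT was -1.772 in BCL6FC, -1.094 in BLIMP1FC and -1.167 in DKO. The median gene was thus lower than in WT in all these groups, which the sum in DKO did not show. CD8 T cell markers summed to 3.34 to 9.96 CPM, NK, innate and gamma delta T cell markers to 19.54 to 38.35 CPM, erythroid and platelet markers (5 genes) to 6.45 to 38.05 CPM, and stromal and epithelial markers (4 genes) to 171.14 to 249.55 CPM over the 16 libraries. Sex-linked genes (2 measured) summed to 235.27 CPM in BCL6FC 2 and 578.31 to 1631.48 CPM in the others. No mitochondrial transcript is listed in the table.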

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

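Of the tests in this part, those of the Treg members that rose, of a mislabelled library, of CD8 T cells and of natural killer cells were chosen only after the results they bear on were seen, and so were the settings that leave out BLIMP1FC 1 and 4 together or WT 4 and BCL6FC 2 together.

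Dixon's criterion at 95% found a library far from the other 3 of its group in 15 of 262 tested sets of 4 values, and chance gives about 1 in 20. The 15 fell in 12 libraries, and BLIMP1FC 3 with 3 of them had the most. In CPM, Ifng was 113 in WT 3 (others 73.5 to 75.3) and 68.3 in BCL6FC 1 (others 93.4 to 97.3), and Ccr2 was 16.2 in DKO 3 (others 86.0 to 96.7). Klf2 was 245 in WT 4 (114 to 134), Il21 was 268 in BCL6FC 1 (219 to 225), Lgals3 was 2.87 in WT 1 (1.74 to 1.84) and Ifit1 was 15.6 in BLIMP1FC 4 (11.2 to 11.4). BLIMP1FC 3 had 10.6 for Gpr83 (7.31 to 7.81), 41.7 for Ccna2 (17.2 to 18.1) and 23.9 for Prc1 (12.3 to 13.6). Gbp2 was 86.0 in BCL6FC 3 (104 to 107), Izumo1r was 662 in BCL6FC 4 (563 to 578), Nfil3 was 232 in BCL6FC 2 (93.0 to 116), and Rn45s was 3530 in WT 2 (1340 to 1690). The TMM factor was 1.01 in BLIMP1FC 2 against 1.03 to 1.04 in the other libraries of that group.

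The effect of the BCL6 alteration differed between the BLIMP1 line and wild type, by a test of the interaction, for 544 genes. The difference on the log2 scale was 1.91 for Eomes (adjusted p = 0.00204), 3.26 for Ccl5 (0.00704), 3.60 for Havcr2 (0.0123), 2.91 for Prdm1 (0.0137), 3.50 for Ctla2a (0.0028), -3.33 for Hspa1b (0.000545), 4.23 for Gzmb (0.027), 1.65 for Il10 (0.0474) and -0.67 for Bcl6 (0.0439). The calls for Gzmb, Il10 and Bcl6 were each lost without some single libraries, with adjusted p of up to 0.0909 without WT 4, 0.0925 without BCL6FC 3 and 0.0889 without BCL6FC 3. Havcr2 lost its call without WT 4 and BCL6FC 2 together (2.97, adjusted p = 0.0567), and Prdm1 without BLIMP1FC 1 and 4 together (3.04, 0.0551). Of 100 drawn splits of the 16 libraries, 3 gave as many genes, the real one included. Such splits also mix the main effects, so they are no test of chance for an interaction. The highest of the others gave 1950 genes, several times the real count, which points to a structure of the samples. That split had 7 of the 8 BCL6FC and DKO libraries on one side, and the remaining split, with 1100 genes, had 6 of the 8, so both lay close to the contrast of means with its 4962 genes.

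Treg and TFR genes were lower in BCL6FC than in WT, with 11 of 26 members called lower. The highest Foxp3 level of a BCL6FC library was 1.10 CPM and the lowest of a WT library 7.36 CPM, which argues against an exchange of WT and BCL6FC libraries. Foxp3 levels overlapped between WT and BLIMP1FC and between BCL6FC and DKO, so an exchange within either pair was not tested. A loss of Foxp3-expressing cells from the sorted pools removes transcripts, and 2 members were called higher, Prdm1 (adjusted p = 0.0124, a call kept without any 1 of the 8 libraries) and, narrowly, Il10 (up to 0.138 without WT 2), so such a loss alone does not account for these 2. For the other members as a set, the changes of BCL6FC and of BLIMP1FC against separate WT libraries had a Spearman rho of -0.38 and -0.55 in the 2 assignments (SE about 0.21; -0.28 and -0.45 over all genes), and a rho above -0.4 in either was to count against fewer Foxp3-expressing cells. Since -0.38 passed that bound by less than its SE, an allowance added after the value was seen, fewer such cells and a lower level per cell cannot be told apart for the set, and an effect on TFH cells of losing TFR cells in the mice, which the design names, was not tested.

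The cytotoxic programme was higher in DKO than in WT, with 21 of 30 members higher and none lower. The DKO minus WT difference was 155 CPM (SE 23.3) for Nkg7 but 0.737 CPM (SE 1.5) for Cd8b1, whose upper 95% limit was 2.37% of the Nkg7 difference. For Fcer1g the limit was 0.554%, but this gene was near the floor, at 0.346 CPM in WT and 0.792 CPM in DKO (log2 fold change 1.19, adjusted p = 0.191). For Klrb1c, a natural killer cell receptor gene at 14.5 CPM in WT and 13.2 CPM in DKO, the limit was 2.49%. These values argue against CD8 T cells as the source by Cd8b1 alone, and Cd8a is not listed. They argue against natural killer cells by Fcer1g and Klrb1c. A sort on CD4 would have removed both cell types, but the labels do not give the gates. Removing each library's trend with exon length took the rho of all genes with length from -0.13 to -0.03 and left the list median at 1.24 from 1.28 (adjusted p = 3.29e-13), so length was not the whole cause. As a hypothesis, CD4 T cells with a cytotoxic programme may be more frequent or more active in the DKO pools, which these data do not separate.

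Transcripts of 10 granulocyte precursor genes summed to 170, 19.4, 0.142 and 144 CPM in BLIMP1FC 1 to 4, to 21.7, 4.87, 0.149 and 10.8 CPM in BCL6FC 1 to 4, and to at most 2.13 CPM in WT and 6.52 CPM in DKO, led by Prg2 and Mpo with means of 20.2 and 15.9 CPM in BLIMP1FC. The 10 genes ranked the 4 BLIMP1FC libraries alike, with a concordance W of 0.96, but this decides nothing about their source, since the genes were chosen after these libraries were seen. Granulocyte precursors among the sorted cells, which a complete sort for CD4 T cells would have removed, and other sources of these transcripts therefore cannot be told apart, and 2 of the genes, S100a8 and S100a9, are also in the S100 and annexin list and the myeloid check list. The level did not follow the group label alone, since BLIMP1FC 3 had 0.142 CPM. In both BLIMP1FC and BCL6FC it was highest in replicate 1, then 4, 2 and 3, while WT was highest in replicate 2 and DKO in replicate 3. This order was noticed after the values were seen, and the labels do not say what a shared number means. Neither this order nor a biological explanation was tested. Without BLIMP1FC 1 and 4 together, 8 genes changed in BLIMP1FC vs WT instead of 561, a setting that also takes 2 of 4 libraries from the group.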

How the results depend on the processing

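Among the settings in this part, leaving out WT 4 with BCL6FC 2 and leaving out BLIMP1FC 1 with BLIMP1FC 4 were chosen only after seeing the data.

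Of 160 named pairs of gene and comparison, 119 kept their direction and their side of the test in every setting that could be run for them, and 41 lost or gained a call or turned in at least 1. DESeq2 changed 3 of 160, all by gaining a call, RLE size factors 1, the strict filter 1 of 156, and a fit of only the compared groups 5 of 129. The median of all genes moved by at most 0.009 (log2) between TMM and RLE. Dropping the filter could show nothing, since the filter had kept all 12117 genes.

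Numbers of changed genes varied most in BLIMP1FC vs WT and in the interaction. DESeq2 called 965 and 1132 genes there, against 561 and 544. With only the libraries of the compared groups, BCL6FC vs WT had 751 genes instead of 1502 and BLIMP1FC vs WT 312. Leaving out WT 4 and BCL6FC 2 gave 253 genes in BLIMP1FC vs WT and 228 in the interaction. In BCL6FC vs WT, to which both libraries belong, the same setting gave 2244 genes instead of 1502. Leaving out BLIMP1FC 1 and 4 gave 8 genes in BLIMP1FC vs WT and 139 in the interaction. In that setting 25 of 78 named pairs lost their call, among them Il4, Tbx21 and Pdcd1 in DKO vs BLIMP1FC. Fewer libraries lower the power of these fits, but lower power cannot give the rise to 2244 genes. Beyond that the cause was not tested.

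Camera with an estimated correlation called 1 list instead of 5 in BCL6FC vs WT, 1 instead of 6 in BLIMP1FC vs WT, 1 instead of 7 in DKO vs WT, 0 instead of 9 in DKO vs BLIMP1FC, 1 instead of 5 in DKO vs BCL6FC, 0 instead of 7 in the contrast of means and 1 instead of 4 in the interaction. At the preset correlation of 0.01, members that vary together count almost as separate evidence, so most list calls rest on that preset. Fry called 8 lists in BCL6FC vs WT and 2 in the interaction, and the cause was not tested.

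Leaving out 1 library in turn gave 745 (without WT 2) to 1922 (without WT 4) genes in BCL6FC vs WT, 183 (without BLIMP1FC 1) to 654 (without BLIMP1FC 3) in BLIMP1FC vs WT, 1392 (without BCL6FC 3) to 3314 (without BCL6FC 4) in DKO vs BCL6FC, and 209 (without DKO 4) to 1478 (without BCL6FC 4) in the interaction. The ranges for DKO vs WT, DKO vs BLIMP1FC and the contrast of means were 2512 to 3335, 4212 to 4733 and 4405 to 5066. Lists called ran from 5 to 6, 4 to 9, 7 to 8, 8 to 9, 4 to 6, 7 to 9 and 3 to 6 in the 7 comparisons. The rho between comparisons that share no library ran from 0.393 (without BCL6FC 4) to 0.566 (without BCL6FC 1) for BCL6FC vs WT with DKO vs BLIMP1FC, and from 0.135 (without BLIMP1FC 4) to 0.274 (without BLIMP1FC 2) for the other pair. The cause was not tested.

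Directions reversed for 3 genes without a call. Il4 in DKO vs WT was -0.19, with a range of -0.40 (without DKO 2) to 0.046 (without WT 2). Tbx21 in DKO vs WT was -0.09, with a range of -0.16 (without WT 2) to 0.015 (without DKO 2). Ifng in BCL6FC vs WT was 0.08, and -0.011 without WT 4 and BCL6FC 2. The cause was not tested.

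The labels do not say what a shared replicate number means. After removing group means, libraries of BCL6FC and BLIMP1FC with the same number correlated at r of 0.18 to 0.32, and 4 of 4 were closest to their own number, as were 3 of 4 between BCL6FC and DKO, while WT showed no such match with BCL6FC or BLIMP1FC. With the replicate number as a block, 1394 genes changed in BCL6FC vs WT, 524 in BLIMP1FC vs WT and 640 in the interaction, and 7 of 160 named pairs lost their call, Eomes, Il10, Il21 and Tbx21 in BCL6FC vs WT, Cxcr5 in DKO vs WT, and Il10 (adjusted p = 0.0792) and Bcl6 (0.0567) in the interaction.

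Depth limits the genes near the floor. In BCL6FC vs WT the log2 fold change had a rho of 0.30 with abundance, and 185 of the 284 genes at least 2-fold lower were among the 20% with the lowest abundance, so counts of strongly lower genes there rest largely on weakly expressed ones. That 20% also held 519 of 851 such genes in DKO vs BLIMP1FC and 374 of 553 in the contrast of means. Of genes at least 2-fold higher, it held 72 of 123 in BLIMP1FC vs WT, 147 of 274 in DKO vs BCL6FC and 39 of 93 in BCL6FC vs WT.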

Other observations

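The 8 gene lists of this part were chosen only after seeing the data, and so was every gene it names. Genes of MHC class I and antigen processing were higher in BCL6FC than in WT, with 12 of 22 measured members higher and none lower (list adjusted p = 2.71e-09, and adjusted p = 0.103 with an estimated correlation). In DKO vs WT 13 were higher and none lower (0.000253, and 0.175 with an estimated correlation), and in DKO vs BLIMP1FC 16 and none (1.99e-06, and 0.15). Psmb8, an immunoproteasome subunit gene, had log2 fold changes of 0.35 in BCL6FC vs WT and 0.53 in DKO vs WT, Tap1, the peptide transporter gene, of 0.40 and 0.47, and H2-K1 of 0.28 and 0.20. B2m had 0.50 in DKO vs WT (adjusted p = 0.00368). S100 and annexin genes had 7 of 18 higher and none lower in BCL6FC vs WT (0.00194, and 0.303 with an estimated correlation), with S100a4, a gene of effector and memory T cells, at 1.52 (adjusted p = 0.000327) and S100a6 at 1.13. Chemokine receptor genes had 6 of 13 higher and 1 lower in DKO vs WT (0.00512, and 0.175 with an estimated correlation), including Cx3cr1, a receptor of cytotoxic effector cells, at 1.91 and Ccr2 at 5.42.

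Ribosomal protein genes had 67 of 81 members higher and 1 lower in DKO than in BLIMP1FC (3.27e-14, and 0.395 with an estimated correlation) and 35 higher and 1 lower in DKO than in WT (3.03e-10, and 0.437). Glycolysis genes had 6 of 20 higher and none lower in BLIMP1FC vs WT (8.94e-08, and 0.2 with an estimated correlation), with Aldoc at a log2 fold change of 1.15, the lactate transporter gene Slc16a3 at 1.44 and Tpi1 at 0.87. Nuclear retained noncoding RNAs had 4 of 7 lower and 1 higher in DKO vs WT (0.043, and 0.175 with an estimated correlation), with Malat1 at -0.74, Neat1 at -1.06 and Rian at -2.01. Integrin genes had 2 of 21 higher and 5 lower in DKO vs WT and no call (0.826). Granulocyte precursor genes had 7 of 10 higher and none lower in BLIMP1FC vs WT and 9 lower in DKO vs BLIMP1FC, counts that restate why the list was chosen.

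Other splits of the libraries were counted for each comparison. For the number of changed genes, 1 of 35 splits, the real one, gave as many in BCL6FC vs WT (1502, highest other 1216), in BLIMP1FC vs WT (561, highest other 7), in DKO vs WT (3478, highest other 4), in DKO vs BLIMP1FC (4978, highest other 1) and in DKO vs BCL6FC (2493, highest other 1). That is under 5% in each, but it is the smallest share that 35 splits can give. No correction was made over these comparisons, which share libraries. In the contrast of means 1 of 100 splits gave as many (4962, highest other 0), in splits that also mix the effect of the BLIMP1 alteration. The split with 1216 genes exchanged WT 4 and BCL6FC 2, which lay nearest each other on the first principal component, at 5.76 and 10.72. Their Foxp3 levels, 8.63 CPM in WT 4 and 0.0974 CPM in BCL6FC 2, went with their labels.

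Chance was not excluded for the number of lists called at the preset correlation. As many lists came from 14 of 35 splits in BCL6FC vs WT (5, highest other 9), 9 of 35 in BLIMP1FC vs WT (6, highest other 8), 9 of 35 in DKO vs WT (7, highest other 10), 5 of 35 in DKO vs BLIMP1FC (9, highest other 9) and 15 of 35 in DKO vs BCL6FC (5, highest other 7). In the contrast of means 15 of 100 splits gave as many (7, highest other 9), and in the interaction 63 of 100 (4, highest other 10), where the splits also mix the main effects and are no test of chance.

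Xist was 235 CPM in BCL6FC 2 and 578 to 1630.7 CPM in the other 15 libraries. Rn45s, a ribosomal RNA precursor, was 6873 and 6875 CPM in BCL6FC 1 and 3 and 655 to 3530 CPM in the other libraries, and Lars2 was 510 and 547 CPM in BCL6FC 1 and 3, 382 CPM in BLIMP1FC 2 and 81.5 to 242 CPM in the others.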
